A study of Mus musculus with 30 samples.

How the data were processed

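RNA-seq was done on cells sorted by flow cytometry from the mouse stomach. Tissue came from the antrum (also called the pylorus), the distal part of the stomach, or from the corpus, its acid-secreting body. The mice carried 1 of 2 reporters. In Lgr5-DTR-GFP mice, cells that express the Wnt target and stem cell marker Lgr5 carry a green fluorescent protein and a diphtheria toxin receptor, and in Sox2-Tomato mice a red fluorescent protein reports the transcription factor Sox2. EpCAM, an epithelial cell adhesion molecule, was a further sort marker in the corpus of Lgr5-DTR-GFP mice. The 30 libraries form 10 groups of 3. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made with the Clontech SMARTer v4 low-input mRNA kit.

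The submitters' processing notes name STAR, HTSeq, DESeq2, edgeR and the mm9 mouse genome build. Their roles and versions are not given in the sources used here, nor is the use of strand in counting, so overlapping and antisense genes cannot be told apart. The expression values are a signal that the authors deposited as gene counts divided by a size factor per library, in a table for the antrum and another for the corpus, and the tables were scaled separately. Per the file headers, the authors' deposited tables of 3 comparisons (antrum Lgr5, antrum Sox2-high against Sox2-low, corpus EpCAM) hold log2 fold changes and adjusted p-values, and that for Sox2 also a fold change column in another unit. A deposited sort sheet gives the sort day and the number of sorted cells of each library. Each expression table has 26400 features. Of these, 433 carry no gene name and hold 0.03 to 0.48% of a library's reads, and 25 carry a calendar date in place of a symbol and hold 0.013 to 0.106%. Both kinds were left out, which leaves 25942 named genes, of which 24663 have their symbol in the reference name table. No coordinates are given, since the reference used here is of another build.

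Within a library, the values are whole multiples of what 1 read is worth. Dividing by that step returned whole reads for at least 99.995% of values above 0 in every library, at a tolerance of 0.01 read. The recovered depth ran from 18672634 to 62344916 reads per library. These reads come from amplified cDNA without molecular identifiers, so a floor of 3 reads covers counting error only. Replicate libraries differed by far more than read sampling noise (lowest chi-square per degree of freedom 34.2), so none was taken as a repeat deposit of another, which does not show that they are separate biological samples.

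The initial design named edgeR's quasi-likelihood test on raw counts. As the deposited values are normalized counts and not raw counts, the main test became limma (empirical Bayes with trend and robust options) on log2(normalized count + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes needed a normalized count of at least 10 in at least 3 libraries of the fit. Fold changes are on this log2 scale, which understates changes of low genes. Groups of the same line and tissue were fitted together: 6 libraries for the antrum Lgr5 and corpus Sox2 sorts and 9 for the antrum Sox2 and corpus Lgr5 sorts. In addition, 2 differences between tissues (the antrum effect minus the corpus effect) were tested over the 15 libraries of a line, on recovered reads rescaled together with TMM factors, because the deposited tables were scaled separately. Sort marker transcripts were also compared by a two-sided exact permutation test, for which 3 against 3 libraries cannot go below 0.1. Where all 3 libraries of a group were at 0, the fold is given as a bound against 3 reads per library.

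Per the sort sheet, libraries with the same number within a line and tissue were sorted on the same day in 12 of 12 combinations, and the sheet's numbers equal those of the labels in 30 of 30 libraries. The numbers therefore pair the libraries. Correlations across genes of the deviations from the group means (sort days 1, 2 and 3) were 0.661, 0.673 and 0.576 for the antrum Lgr5 sorts, 0.582, 0.317 and 0.431 for Sox2-high with Sox2-low, 0.484, 0.126 and 0.324 for Sox2-high with Sox2-negative, and 0.586, 0.432 and 0.515 for Sox2-low with Sox2-negative. In the corpus they were 0.221, 0.366 and 0.355 for Sox2, 0.0482, 0.135 and 0.159 for EpCAM-high with EpCAM-low, 0.0336, 0.0272 and -0.0563 for EpCAM-high with Lgr5-negative, and 0.0709, 0.0676 and -0.044 for EpCAM-low with Lgr5-negative. The fit with the sort day as a block was an alternative, so the main p-values count differences shared by a sort day as spread between libraries. The sources used here do not say how many animals a sort pooled or whether days used separate animals, so p-values measure the spread between these sorts.

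The gene lists, the naming rule, the comparisons and a first set of other settings were chosen before the data were examined. The 22 lists hold markers of Lgr5 stem cells with Wnt targets, other proposed stem or isthmus cells, chief, mucous neck, pit, parietal, enteroendocrine and tuft cells, genes of S phase, G2/M phase, ribosome biogenesis, endoplasmic reticulum folding, oxidative phosphorylation, the Notch pathway and immediate early stress, and markers of general epithelium, immune and red blood cells, fibroblasts with smooth muscle, endothelium, enteric glia and neurons, squamous forestomach epithelium and intestine. Each list with at least 3 measured members was tested with limma's camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated per list. Members were counted after adjustment over all genes and after adjustment over the list alone. Several markers belong to more than 1 cell type, and the stomach itself expresses members of the intestine, Notch and nerve lists.

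Named genes are Lgr5, Sox2 and Epcam in every comparison. Further names go to the genes with the largest absolute log2 fold changes in each direction, 10 in the main comparisons and 5 in the others, among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the groups' libraries. The last condition was dropped for the tissue differences. Unnamed gene models, small RNAs, mitochondrial genes and receptor segments were left out. Per list, up to 4 members with the smallest adjusted p are named, or up to 2 of the highest expressed where no member passed. Some genes that this rule takes are not reported here.

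The settings chosen in advance were no filter on low values, DESeq2 on the recovered reads, edgeR with RLE size factors, limma-voom with sample quality weights, all libraries of a tissue in a single fit, the sort-day block, an estimated list correlation, sort markers on a log2(CPM + 1) scale, and each library left out in turn. After the data were seen, edgeR with TMM factors with and without the block, TMM scaling of the recovered reads, pseudocounts of 8 and 0.5, a fit without antrum sort day 1 and leaving out libraries for the list counts were added. Of these, edgeR with TMM factors and no block is the test that the initial design named, here run on recovered reads. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

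The fits were tested on simulated counts with 200 changed genes per comparison. Of genes changed 4-fold, limma recovered 9% in the antrum Lgr5 comparison, 10% for Sox2-high against Sox2-low, 31% for Sox2-high against Sox2-negative, 17% for Sox2-low against Sox2-negative, 67% for EpCAM-high against EpCAM-low, 64% for EpCAM-high against Lgr5-negative, 77% for EpCAM-low against Lgr5-negative, 90% in the corpus Sox2 comparison, and 11% and 12% in the Lgr5 and Sox2 tissue differences. DESeq2 was simulated in the antrum Lgr5 comparison only, where 33.6% of its calls were false. Of the limma calls, 10% were false there, 12.8% for EpCAM-high against Lgr5-negative and 8.88% in the corpus Sox2 comparison. The share was 8.33% in the Lgr5 tissue difference, 5.26% for Sox2-low against Sox2-negative and 0 to 4.71% in the others. Lists of 20 randomly drawn genes, raised in simulation, passed camera with an estimated correlation in 20 of 20 draws in each of the 8 comparisons. The threshold there was an unadjusted p under 0.05. Random genes need not share the correlation of marker lists, estimated at 0.564 for tuft cell genes in Sox2-high against Sox2-low. The draws therefore do not show how often a raised marker list would pass.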

Results

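Transcriptomes were measured in 30 libraries of sorted mouse stomach cells, in 10 groups of 3 sort days each. Antrum of Lgr5-DTR-GFP mice gave Lgr5-positive and Lgr5-negative cells, and antrum of Sox2-Tomato mice gave Sox2-high, Sox2-low and Sox2-negative cells. Corpus of Lgr5-DTR-GFP mice gave Lgr5-positive cells with high or low EpCAM and Lgr5-negative cells, and corpus of Sox2-Tomato mice gave Sox2-positive and Sox2-negative cells. The EpCAM-low libraries held 31985198 to 62344916 reads, and the other libraries 18672634 to 34437305. Sorted cells were fewest in the Sox2-high (1630 to 3268 per library) and EpCAM-high libraries (2580 to 5230). In the EpCAM-low libraries, 10 genes took 81.6 ± 6.22% of the reads (SD, n = 3) and pepsinogen C (Pgc) alone 43.1 ± 4.29%, against 35.1 ± 4.77% and 19.0 ± 3.31% in the EpCAM-high libraries. Reads were found for 15014 to 16299 genes in the EpCAM-low libraries and for 17749 to 21694 genes in the others. Values are normalized counts, as mean ± SD of 3 libraries, and log2 fold changes are given with their standard error (SE). Adjusted p-values of genes are from limma and those of gene lists from camera, both with Benjamini-Hochberg (BH) adjustment. Every gene said to have risen or fallen moved in the same direction on 3 of 3 sort days.

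The transcripts behind the sort gates were examined first. Lgr5 was at 4226 ± 1480 normalized counts in antrum Lgr5-positive and 194.5 ± 127.5 in Lgr5-negative libraries (log2 fold change 4.64, SE 0.59, limma BH adjusted p = 0.0784, and 0.00991 with the sort-day block). In the corpus, Lgr5 was at 4205 ± 2023 in EpCAM-high and 2041 ± 967.4 in EpCAM-low Lgr5-positive libraries, against 83.27 ± 23.3 in Lgr5-negative libraries. It rose in both positive groups (5.58 and 4.53 log2 units, SE 0.40 for both, limma BH adjusted p = 0.000161 and 0.00023, and 2.15 for EpCAM-low on log2(CPM + 1) values). Sox2 was at 2611 ± 1155 in antrum Sox2-high, 581.6 ± 181.1 in Sox2-low and 260.7 ± 206 in Sox2-negative libraries. The Sox2-high libraries differed from Sox2-low by 2.10 log2 units (SE 0.83, limma BH adjusted p = 0.169, 0.0124 with the block) and from Sox2-negative by 3.81 (SE 0.83, 0.0538, and 0.00316 with the block). Sox2-low differed from Sox2-negative by 1.71 (SE 0.83, limma BH adjusted p = 0.836). In the corpus, Sox2 rose from 52.48 ± 22.53 in Sox2-negative to 341.4 ± 63.05 in Sox2-positive libraries (2.76 log2 units, SE 0.35, limma BH adjusted p = 0.00121). Epcam was at 32534 ± 5651 in EpCAM-high, 7795 ± 1159 in EpCAM-low and 15096 ± 732.8 in Lgr5-negative corpus libraries. In two-sided exact permutation tests the marker of the sort gave p = 0.1 in each of these comparisons, the smallest value that 3 against 3 libraries allow, except Sox2-low against Sox2-negative with exact p = 0.2.

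**Figure D1:**
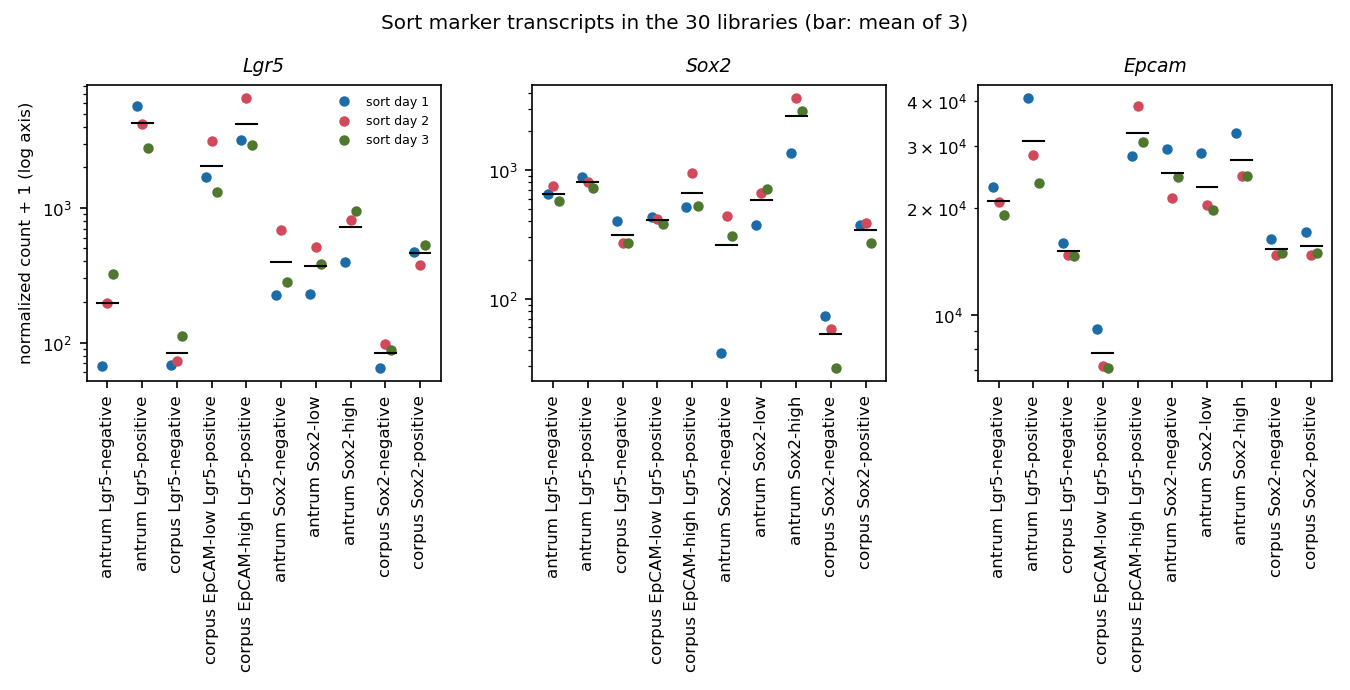
Normalized counts + 1 (log axis) of Lgr5, Sox2 and Epcam in the 30 libraries, with 1 point per library coloured by sort day and a bar at the mean of 3. Lgr5 means run from 83.27 in corpus Lgr5-negative to 4205 in corpus EpCAM-high libraries within the corpus Lgr5-DTR-GFP sorts, and the Sox2-high libraries have the highest Sox2 mean, 2611.

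The antrum Lgr5 sort asked which transcripts mark Lgr5-positive cells of the antral gland. Beside Lgr5, several deep gland and secretory genes had higher means in positive libraries. The water channel Aqp5 was at 38819 ± 13220 in positive and 3931 ± 1112 in negative libraries, pepsinogen C (Pgc) at 3985219 ± 2634798 and 233724 ± 97168, and the apolipoprotein Apoa1 at 4000 ± 1868 and 94.73 ± 20.28. Somatostatin (Sst), the hormone of D cells, was at 12691 ± 9449 in positive and 71476 ± 55189 in negative libraries. By limma without the sort-day block no gene passed: 0 of 14047 genes were called, with 1017 at an unadjusted p under 0.05. The 2 edgeR fits without a block also called 0. Limma with the sort-day block called 446 (352 higher, 94 lower) and edgeR with the block 400 (337 higher, 63 lower). DESeq2 called 373 (315 higher, 58 lower), voom with quality weights 169 (154 higher, 15 lower), the fit over all antrum libraries 77 and the fit without a filter 12. Without Lgr5-positive library 1 or 3, limma called 3 or 4 genes. With the block, the limma BH adjusted p was 0.00859 for Aqp5 (log2 fold change 3.29, SE 0.36 and adjusted p = 0.0719 without it), 0.00926 for Pgc (3.97, SE 0.56, 0.0928), 0.00514 for Apoa1 (5.27, SE 0.45, 0.0644) and 0.00514 for Sst (-2.50, SE 0.68, 0.357).

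As lists, the antral Lgr5-positive libraries had higher medians for stem and gland-base genes and lower medians for endocrine and cycling genes. No member of any list passed over all genes, and counts adjusted over the list alone follow. The Lgr5 stem cell and Wnt target list had a median log2 fold change of 1.60 over 20 members, of which 11 rose adjusted over the list alone, with the ion transporter Slc12a2 at 2.22 (SE 0.53, camera BH adjusted p of the list = 7.8e-17, adjusted p = 0.0893 with an estimated correlation). This list includes Lgr5, the sorted gene, so part of its result follows from the gate. Chief cell genes had a median of 2.84 (6 of 9 rose over the list alone, camera BH adjusted p = 5.23e-12, adjusted p = 0.0502 with an estimated correlation). Parietal cell genes had a median of 2.28 (10 of 14, camera BH adjusted p = 2.82e-15, adjusted p = 0.0893 with an estimated correlation), although their highest expressed members Car2 (-0.20) and the chloride channel protein Clic6 (0.82) lay lower. Mucous neck genes had a median of 1.60 (3 of 8, camera BH adjusted p = 1.83e-06, adjusted p = 0.0893 with an estimated correlation), with the trefoil factor Tff2 at 1.83 (SE 0.69) and the gastrokine Gkn3 at 3.31 (SE 0.74). Intestine genes (3 of 9, camera BH adjusted p = 0.000247), other proposed stem or isthmus markers (0.45, 1 of 11, 0.00601) and endoplasmic reticulum genes (0.08, 0.0492) also passed as higher. For these lists, camera gave BH adjusted p = 0.0893, 0.171 and 0.171 with an estimated correlation, in that order. Among the stem markers, Sox9 was at 1.51 (SE 0.35) and Prom1 at 1.12 (SE 0.59). With the block, limma BH adjusted p was 0.0149 for Slc12a2, 0.0419 for Tff2, 0.0154 for Gkn3, 0.0262 for Sox9 and 0.0213 for Prom1, which did not pass without it (0.265, 0.626, 0.237, 0.247 and 0.777).

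On the lower side in the antral Lgr5-positive libraries, enteroendocrine genes had a median of -1.27 (4 of 25 fell adjusted over the list alone, camera BH adjusted p = 5.23e-12, adjusted p = 0.171 with an estimated correlation), while gastrin (Gast) was at 0.68 (SE 0.78). S phase genes had a median of -0.80 (camera BH adjusted p = 1.61e-09) and G2/M genes of -0.82 (1.23e-09), with adjusted p = 0.149 and 0.0893 with an estimated correlation, and none of their 26 and 24 members passed over the list alone. Examples are the licensing factor Mcm6 (-0.88, SE 0.58), cyclin Ccna2 (-0.99, SE 0.43) and the mitotic activator Cdc20 (-0.97, SE 0.33). Ribosome biogenesis genes (median -0.55, camera BH adjusted p = 6.38e-07), pit cell genes (-0.59, 0.0466), glia and neuron genes (-1.04, 0.05) and squamous genes (-1.19, 0.0492) passed as lower. In camera they had BH adjusted p = 0.0502, 0.556, 0.171 and 0.31 with an estimated correlation, in that order. With the block the glia and squamous lists gave camera BH adjusted p = 0.0724 and 0.0608. The tuft cell (median 0.26) and general epithelium lists (-0.30) went from 0.0975 and 0.0722 to 0.0348 each. The oxidative phosphorylation (0.22), Notch (-0.39), immune (-0.46) and endothelium (0.63) lists did not pass. Neither did immediate early stress, whose median was -0.04 with a test upward, or fibroblasts, whose 3 members had a median of -0.28 and a mean of 0.20. The pericyte gene Rgs5 of that last list was at 1233 ± 554.5 in positive and 102.8 ± 120.9 in negative libraries (adjusted p = 0.196, and 0.0175 with the block, limma BH).

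In the antrum Sox2 sorts, the Sox2-high cells were compared with Sox2-low cells, a comparison for which the authors also deposited a table. Serotonin and granule genes of endocrine cells were among those that rose in the Sox2-high libraries. Tryptophan hydroxylase 1 (Tph1), the rate-limiting enzyme of serotonin synthesis in gut endocrine cells, was at 288121 ± 117076 in Sox2-high and 772.2 ± 643.2 in Sox2-low libraries (log2 fold change 9.06, SE 1.02, limma BH adjusted p = 0.00219). The granins Chga (608606 ± 116014 against 7320 ± 2883) and Chgb (1551102 ± 221467 against 19019 ± 5304), the opioid precursor Penk (51596 ± 22467 against 201.1 ± 143.3) and the transcription factor Nkx6-1 (6864 ± 1335 against 28.47 ± 13.38) rose with it. The incretin hormone Gip fell from 2396 ± 1614 to 47.6 ± 49.13, and tuft cell genes such as the kinase Dclk1 and the phospholipase Plcb2 fell by 5.10 and 4.40 log2 units.

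Between Sox2-high and Sox2-low libraries, 1190 of 15064 genes passed (limma, BH), 925 higher and 265 lower, and 1168 of them changed more than 2-fold. The carbonic anhydrase Car4 (7.36, SE 0.79), Nov (6.93, SE 0.46), the pentraxin Nptx2 (6.82, SE 0.49), the collagen Col8a1 (6.76, SE 0.46) and the Wnt inhibitor Wif1 (6.65, SE 0.54) also rose. For these and the 5 risen genes given with their counts, limma BH adjusted p ran from 9.45e-05 (Nkx6-1) to 0.00219 (Tph1). Beside Gip, falls with adjusted p from 0.00908 (Gip) to 0.0404 (Sh2d6) by limma with BH included Cd300lf (-5.62, SE 1.34), Dclk1 (-5.10, SE 1.25), the transcription factor Spib (-4.30, SE 0.89), the exchange factor Vav1 (-3.90, SE 0.95), Lrmp (-3.87, SE 0.92), Sh2d6 (-3.74, SE 0.92), Pik3r5 (-3.53, SE 0.85) and Fyb (-3.35, SE 0.80). The share of higher genes was 77.7% here, 56.9% of 4581 calls with the sort-day block, 64.6% of 2457 calls by DESeq2. The voom fit called 6255 genes (3449 higher, 2806 lower). Without Sox2-low library 1, 2 or 3 the count was 430, 377 or 421, of which only 38, 27 or 28 were lower. Without Sox2-high library 2 or 3 it was 239 or 406, with 37 or 99 lower. Of the 54 genes named in this comparison, 17 passed whichever library was left out, among them Gip and these 10 risen genes. Each of 5 libraries, left out alone, ended 21 to 33 calls.

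By list, 15 of 25 enteroendocrine genes rose from Sox2-low to Sox2-high and 2 fell (15 and 4 adjusted over the list alone), with a median of 2.23 (camera BH adjusted p = 3.76e-06, adjusted p = 0.274 with an estimated correlation) and the amine-forming decarboxylase Ddc at 3.68 (SE 0.37). Among 19 tuft cell genes 10 fell (19 over the list alone), with a median of -3.71 (camera BH adjusted p = 1.09e-13, adjusted p = 0.197 with an estimated correlation), including the phospholipase Plcb2 (-4.40, SE 0.62), Gfi1b (-5.98, SE 1.14) and the prostaglandin synthase Ptgs1 (-3.23, SE 0.67). In the G2/M list 9 of 24 genes fell (16 over the list alone), among them Cdc20 (-1.40), Tpx2 (-1.47), Hmmr (-1.48) and Ccnb2 (-1.50), with a median of -1.21 (camera BH adjusted p = 1.5e-12, adjusted p = 0.197 with an estimated correlation). Among 26 S phase genes 3 fell, Chaf1b (-1.25), Ccne1 (-1.50) and Cdt1 (-1.44), also over the list alone, with a median of -1.01 (camera BH adjusted p = 2.3e-08, adjusted p = 0.274 with an estimated correlation). Ribosome biogenesis genes (median -0.70, 1 of 23 fell, Myc at -1.11, also over the list alone) and pit cell genes (-1.19, 2 of 13 fell, Muc5ac at -1.89 and Dpcr1 at -1.92, 8 over the list alone) passed as lower with camera BH adjusted p = 1.74e-07 and 1.76e-05. Camera gave them BH adjusted p = 0.197 with an estimated correlation for each. Oxidative phosphorylation genes had a median of -0.39, and none of 22 passed (camera BH adjusted p = 0.00869, adjusted p = 0.704 with an estimated correlation).

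Markers of other cell types moved too. The nerve and glia list, parts of which endocrine cells express, had a median of 1.68, and 5 of 9 genes rose, also over the list alone (camera BH adjusted p = 0.00903, 0.0896 with the block, and adjusted p = 0.197 with an estimated correlation), with Ncam1 at 3.09, Elavl4 at 3.23, Ret at 2.77 and Tubb3 at 1.68. Of 3 fibroblast genes, Col1a2 rose from 0.674 ± 1.17 to 258.7 ± 93.04 and 2 rose over the list alone (median 2.19, camera BH adjusted p = 0.0329, 0.102 with the block, and adjusted p = 0.197 with an estimated correlation). Endothelial genes went both ways (median 0.93, Vwf 3.15, Esam 1.66, Tek -3.72) and immune genes had a median of -0.23 with none of 14 passing. Other lists did not pass. Stem and Wnt genes had a median of 0.35 (1 rose, Wif1). Among the rest were other stem markers (median 0.02, Hopx at 2.16 and Runx1 at -1.19, mean 0.25, test downward, and median -0.04 with TMM scaling), chief (0.31), mucous neck (-0.37), parietal (-0.51, Ckb at 2.80), endoplasmic reticulum (-0.18, mean 0.16, Atf6 at 3.62), Notch (-0.56, mean 0.30, Mfng at 2.24 and Hes5 at 3.75). The remaining lists were immediate early (-0.22, Dusp1 at 1.57 and Klf6 at -0.88), epithelium (-0.38, Krt7 at 1.03, Cldn3 at 2.15 and Krt8 at -1.24), squamous (-1.23, Lor at 3.10) and intestine (-0.46). Lgr5 differed by 0.93 (SE 0.52, limma BH adjusted p = 0.331, 0.0358 with the block) and Epcam by 0.26 (0.644).

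**Figure D2:**
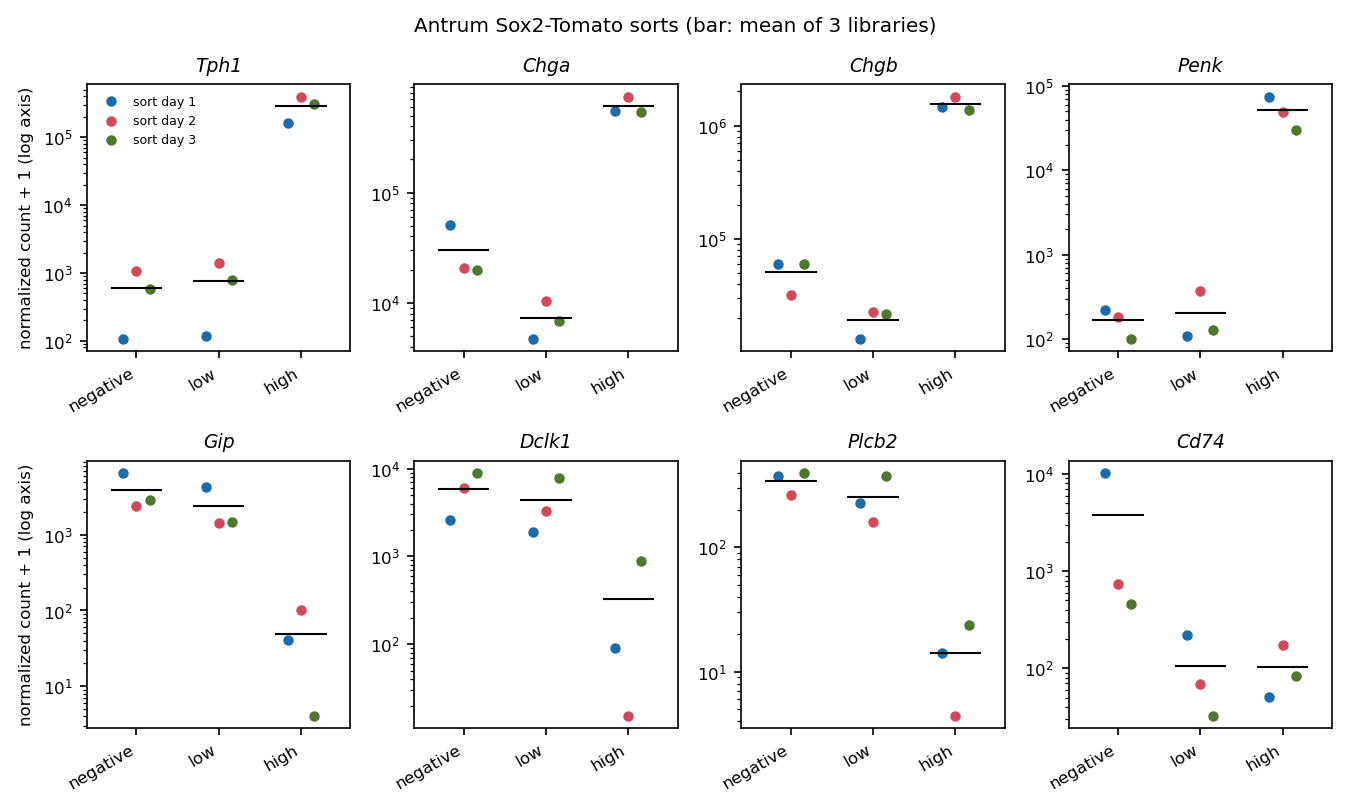
Normalized counts + 1 (log axis) of 8 genes in the antrum Sox2-negative, Sox2-low and Sox2-high libraries, with 1 point per library coloured by sort day and a bar at the mean of 3. Tph1, Chga, Chgb and Penk are highest in the Sox2-high libraries (Tph1 mean 288121), Gip is lowest there (mean 47.6), and Cd74 has a mean of 3804 with an SD of 5551 in Sox2-negative libraries.

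Sox2-high libraries were also compared with Sox2-negative libraries, where 4 of 25 enteroendocrine genes rose and 1 fell (camera BH adjusted p of the list = 0.479 with an estimated correlation). Tph1 (9.38, SE 1.02), Penk (8.25, SE 0.53), Nkx6-1 (7.55, SE 0.40), Nptx2 (6.88, SE 0.49) and Col8a1 (5.98, SE 0.46) rose. For these genes, limma BH adjusted p ran from 0.000105 (Nkx6-1) to 0.00209 (Tph1). Gip (-7.11, SE 1.03), pancreatic polypeptide Ppy (-5.22, SE 1.10), Spib (-4.87, SE 0.89) and peptide YY (Pyy, -4.34, SE 0.74) fell. Their limma BH adjusted p ran from 0.00962 (Gip) to 0.0475 (Ppy), and the calls of Ppy, Spib and Pyy ended without 5, 3 and 3 of the 6 libraries, each left out alone (highest adjusted p = 0.142, 0.1 and 0.0945). In all, 324 genes passed (limma, BH), 215 higher and 109 lower (66.4% higher). The sort-day block called 1463 (811 higher, 652 lower), DESeq2 1050 (569 higher, 481 lower) and voom 1493. The edgeR fits called 200 with TMM factors (154 higher, 46 lower) and 204 with RLE factors. Without Sox2-negative library 1, 2 or 3 the count was 214, 162 or 150 (82.2, 75.9 or 81.3% higher), and without Sox2-high library 2 it was 87 (62.1% higher). Without Sox2-high library 3 the majority turned, with 63 higher and 70 lower among 133. Of the named genes, 13 of the 24 calls passed whichever library was left out. These 2 comparisons share the Sox2-high libraries, so their fold changes are not independent.

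Among lists, tuft cell genes were lower in Sox2-high than in Sox2-negative libraries (median -3.93, 5 of 19 fell, 19 over the list alone, Plcb2 at -4.89, camera BH adjusted p = 4e-22, adjusted p = 0.12 with an estimated correlation). Immune genes had a median of -4.07 (none of 14 passed, 12 fell over the list alone, camera BH adjusted p = 9.27e-12, adjusted p = 0.12 with an estimated correlation), with the antigen presentation gene Cd74 at 101.9 ± 63.38 against 3804 ± 5551 (limma BH adjusted p = 0.125, and 0.0326 with the block). Enteroendocrine genes had a median of 0.81, and 4 rose (Chga at 4.45 among them) and 1 fell (Isl1 at -2.97), or 6 and 4 over the list alone (camera BH adjusted p = 0.0124, adjusted p = 0.479 with an estimated correlation). Parietal (median -2.45, 1 fell, Kcnj16, 6 over the list alone), pit (-0.78, 3 fell over the list alone) and intestine genes (-1.40) passed as lower with camera BH adjusted p = 1.19e-05, 1.19e-05 and 0.026 (0.0525 with the block for intestine). By camera their values were BH adjusted p = 0.173, 0.12 and 0.382 with an estimated correlation, in that order. G2/M (-0.47), S phase (-0.44), ribosome biogenesis (-0.25) and immediate early genes (-0.25) passed as lower with camera BH adjusted p = 0.000112, 0.00511, 0.00511 and 0.0323. For these lists, camera gave BH adjusted p = 0.382, 0.479, 0.424 and 0.382 with an estimated correlation, in that order. Stem and Wnt genes (0.41, Wif1 at 4.92), fibroblast (2.03, Col1a2 at 6.76) and glia genes (1.18, Tubb3 at 2.38) passed as higher with camera BH adjusted p = 0.00637, 0.0013 and 0.00347. In camera they had BH adjusted p = 0.329, 0.12 and 0.12 with an estimated correlation, in that order. The epithelium list (-0.25, 0.131) passed with the block (0.017). Other lists did not pass, and in 3 of them the median and the mean differed in sign: endoplasmic reticulum (-0.11 and 0.11), Notch (-0.27 and 0.13) and endothelium (0.64 and -0.39).

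Between Sox2-low and Sox2-negative libraries of the antrum no single gene passed by limma, while lists of endocrine, immune and cycling genes passed at the preset correlation only (camera BH adjusted p from 0.213 to 0.221 with an estimated one). Gastrin (Gast) was at 355559 ± 157613 in Sox2-low and 2324078 ± 2450241 in Sox2-negative libraries, and Chgb at 19019 ± 5304 and 50229 ± 16188. By limma, 0 genes passed and 966 had an unadjusted p under 0.05. The count was also 0 with the block and in each of the 3 edgeR fits, 241 by DESeq2 (5 higher, 236 lower) and 321 by voom (7 higher, 314 lower). Enteroendocrine genes had a median of -1.41 (14 fell and 1 rose over the list alone, camera BH adjusted p = 2.06e-12, adjusted p = 0.213 with an estimated correlation), immune genes of -3.96 (10 fell over the list alone, 9.6e-13, adjusted p = 0.213 with an estimated correlation) and parietal genes of -2.01 (4 fell over the list alone, 4.45e-05, adjusted p = 0.221 with an estimated correlation). G2/M (0.76), S phase (0.61), ribosome biogenesis (0.42), oxidative phosphorylation (0.25) and mucous neck genes (0.67) passed as higher. They had camera BH adjusted p = 7.69e-15, 3.29e-10, 4.33e-08, 0.00485 and 0.0156. Camera gave them BH adjusted p = 0.213, 0.221, 0.221, 0.608 and 0.221 with an estimated correlation, in that order. Cdc20 was at 0.74 (SE 0.28), Cd74 at -4.27 (SE 1.14) and Tff2 at 0.89 (SE 0.75). Tuft cell genes had a median of -0.37 and, like the remaining 13 lists, did not pass. Stem and Wnt genes had a median of -0.02 (0.01 with TMM scaling) and a mean of 0.02. Median and mean differed in sign for endoplasmic reticulum (0.02 and -0.05), epithelium (0.09 and -0.08) and fibroblast genes (-0.17 and 0.05), and Notch genes had a median of -0.15 and a mean of -0.17 with a test upward.

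In the corpus, EpCAM-high and EpCAM-low Lgr5-positive cells were compared, again a pair named in a table by the authors. Medians of tuft cell and epithelial genes were higher in the EpCAM-high libraries, and those of chief cell, parietal cell and mitochondrial genes in the EpCAM-low libraries (camera BH adjusted p from 0.283 to 0.504 with an estimated correlation). Among tuft genes, the receptor Il17rb was at 1598 ± 249.9 in EpCAM-high and 42.56 ± 30.67 in EpCAM-low libraries, and leukotriene C4 synthase (Ltc4s) at 6728 ± 1538 and 161.3 ± 136.6 (log2 fold changes 5.41 and 5.66, SE 0.46 and 0.49, limma BH adjusted p = 6.78e-05 and 7.15e-05). Gastric intrinsic factor (Gif), a chief cell product in the mouse, was at 123893 ± 15741 and 1294910 ± 445715, and the proton pump subunit Atp4a of parietal cells at 184628 ± 180710 and 1057610 ± 418472. Epcam itself rose by 2.06 (SE 0.17, limma BH adjusted p = 6.72e-05), and Lgr5 and Sox2 differed by 1.04 (SE 0.40, 0.0707, and 0.0437 with the block) and 0.64 (0.119). On log2(CPM + 1) values Epcam, Lgr5 and Sox2 differed by 4.06, 2.98 and 2.33. A fall in EpCAM-high libraries on the deposited scale therefore need not be a fall in the share of reads.

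Of 14847 genes, 4714 passed (limma, BH), 2595 higher and 2119 lower in EpCAM-high libraries, and 3563 changed more than 2-fold. TMM scaling moved the median of all genes by 0.10 log2 units and gave 2896 higher and 1749 lower. Genes that rose included Lrrtm3 (8.56, SE 1.14), Hap1 (7.86, SE 0.91), Ank (7.47, SE 1.30), the transcription factor Prox1 (7.06, SE 1.13), Pcolce2 (6.98, SE 1.07), Ripor2 (6.93, SE 1.38), the leukocyte phosphatase Ptprc (6.91), Inpp5d (6.79, SE 0.59) and Ildr1 (6.76, SE 0.54). For these genes, limma BH adjusted p ran from 5.45e-05 (Ildr1) to 0.00739 (Ptprc). Genes that fell included Mug1 (-4.15, SE 0.48), Aldh1l2 (-4.06, SE 0.63), Uqcrh (-4.04, SE 1.13), the growth factor Egf (-4.04, SE 0.57), the acidic chitinase Chia1 (-3.87, SE 0.37), Tmed6 (-3.80, SE 0.34), osteopontin Spp1 (-3.74, SE 0.94), Sostdc1 (-3.73, SE 0.33), the helicase Blm (-3.69, SE 0.30) and Derl3 (-3.62, SE 0.40). Their limma BH adjusted p ran from 5.87e-05 (Blm) to 0.0232 (Uqcrh). Mug1, Uqcrh and Chia1 have close paralogs or pseudogenes, so their values are uncertain. Without EpCAM-high library 2 the count was 2985. Of the named genes, 74 of the 85 calls passed whichever library was left out.

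Tuft cell genes rose in 19 of 20 cases, also over the list alone, with a median of 5.66 (camera BH adjusted p = 3.13e-12, adjusted p = 0.504 with an estimated correlation), including Sh2d6 (5.84) and Alox5ap (5.57). Epithelial genes had a median of 0.91, with 10 of 20 higher and 1 lower (12 and 1 over the list alone), among them the keratins Krt8 (2.17) and Krt18 (2.21) and claudin Cldn7 (5.30, camera BH adjusted p = 0.000211, adjusted p = 0.283 with an estimated correlation). Oxidative phosphorylation genes fell in 20 of 22 cases (22 over the list alone), with cytochrome c (Cycs) at -1.96, Uqcrc2 at -1.53, Ndufs1 at -1.17 and Atp5a1 at -1.29 (median -1.36, camera BH adjusted p = 3.15e-08, adjusted p = 0.504 with an estimated correlation). Parietal genes fell in 13 of 15 cases, also over the list alone, with the water channel Aqp4 at -2.48, Esrrg at -2.67 and Atp4a at -3.10 (median -2.48, camera BH adjusted p = 1.08e-05, adjusted p = 0.504 with an estimated correlation). Chief cell genes fell in 6 of 10 cases, also over the list alone, with Gif at -3.33, the colipase Clps at -3.39 and Copz2 at -3.25 (median -3.26, camera BH adjusted p = 0.00697, adjusted p = 0.504 with an estimated correlation). In the endoplasmic reticulum list 11 of 20 fell and 1 rose (13 and 3 over the list alone), with Ssr4 at -2.02, Dnajc3 at -1.24, Xbp1 at -1.07 and Sdf2l1 at -1.22, and ribosome biogenesis had 1 of 23 lower, Bop1 at -0.54 (0 over the list alone). Their medians were -0.69 and -0.44 (camera BH adjusted p = 0.00697 and 0.0224, each with adjusted p = 0.504 with an estimated correlation).

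Lists that went both ways or did not pass by camera still held large changes. In the Notch list 6 of 13 genes rose (6 and 1 lower over the list alone, median 2.65, camera BH adjusted p = 0.0781), with the ligands Dll1 (7.42) and Jag2 (4.55) and the modifier Lfng (3.24). Dll4 was at least 37.8-fold higher, as all EpCAM-low libraries were at 0. In the stem and Wnt list 5 rose and 6 fell (6 and 6 over the list alone, median -0.17 against a mean of 0.57), with Wif1 at least 44.2-fold higher, Nkd1 at 4.02, Ascl2 at 3.26 and Slc12a2 at -1.38. Other stem markers also split (3 higher, 2 lower, median 0.43, or 0.25 with genes at 0 in a group set at their bound), with Hopx at 5.18, Runx1 at 2.14, Sox9 at 2.28 and Lrig1 at -1.83. Pit (1.25, Tff1 at 1.69, Psca at -2.47), enteroendocrine (0.65, Cpe at 4.46, Isl1 at -1.96), immediate early (0.46, Klf6 at 1.68, Jun at -1.78), G2/M (0.72, Cenpe at 2.18), S phase (0.02, with a test downward, Pola1 at 4.83, Cdc45 at -1.66) and mucous neck genes (0.03, 0 of 8 passed) did not pass. Immune genes had a median of 2.24, or 2.04 at the bound, and 4 of 13 rose, Ptprc, Coro1a (6.60), Cd79b (4.43) and Alas2 (5.84). Glia and neuron genes had a median of 2.32, or 1.16 at the bound, with 2 of 8 higher (L1cam at 5.27, Ncam1 at 3.77). Endothelial genes had a median of -0.51 and a mean of 0.62 (Tek at 5.08, Esam at 1.29), and squamous genes of 0.53 and -0.24. The 1 measured fibroblast gene, Dcn, was at -4.86. The intestine list had a median of -0.55, a mean of 1.19 and, with TMM scaling, a median of 1.29. Its risen members were Vil1 at 4.99, Apob at 4.25, Cdx1 at least 12.8-fold and Alpi at least 2.61-fold higher. The immediate early gene Hspa1a (2.92) shares reads with Hspa1b, so its value is uncertain.

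**Figure D3:**
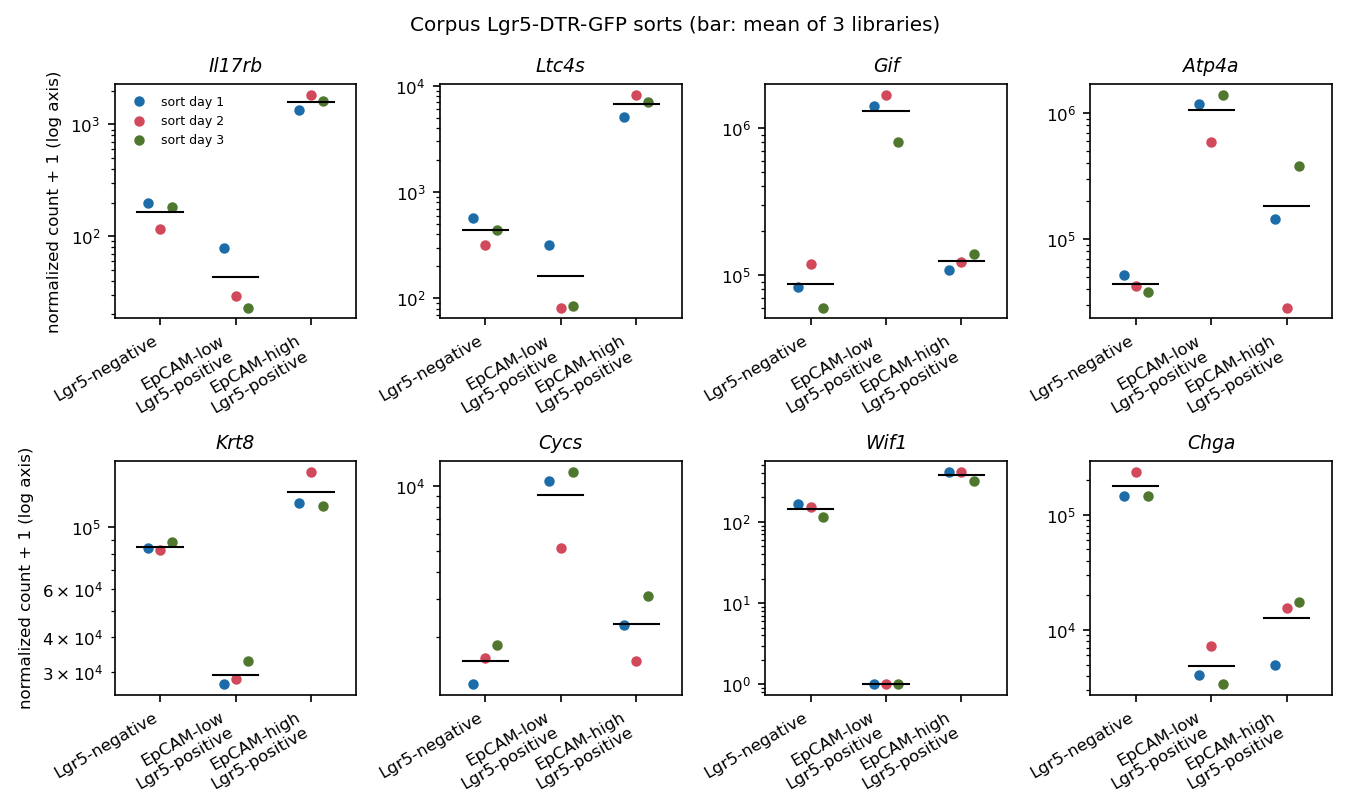
Normalized counts + 1 (log axis) of 8 genes in the corpus Lgr5-negative, EpCAM-low and EpCAM-high Lgr5-positive libraries, with 1 point per library coloured by sort day and a bar at the mean of 3. Il17rb and Ltc4s are highest in EpCAM-high libraries (means 1598 and 6728), Gif, Atp4a and Cycs in EpCAM-low libraries (means 1294910, 1057610 and 9120), and Chga in Lgr5-negative libraries (mean 176165).

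Compared with Lgr5-negative corpus cells, the EpCAM-high Lgr5-positive libraries had a higher median of tuft cell genes and lower medians of endocrine, neck and cycling genes (camera BH adjusted p from 0.152 to 0.315 with an estimated correlation). Ficolin A (Fcna, 6.13, SE 0.43), Lgr5 (5.58), the protocadherins Pcdh20 (5.17, SE 0.69) and Cdhr5 (4.70, SE 0.38) and the Wnt feedback gene Nkd1 (4.74, SE 0.34) rose. Chgb (-4.38, SE 0.71), the lipase Cel (-4.25, SE 0.48), Chga (-3.95, SE 0.47), ghrelin (Ghrl, -3.90, SE 0.51) and the monoamine transporter Slc18a2 (-3.78, SE 0.49) fell. For these genes, limma BH adjusted p ran from 0.000161 (Lgr5) to 0.00321 (Chgb). Sox2 rose by 1.03 (SE 0.29, limma BH adjusted p = 0.032), and Epcam by 1.09 (SE 0.17, 0.00282). The call of Sox2 ended without Lgr5-negative library 2 or 3 or EpCAM-high library 2, where its log2 fold change was 0.94, 0.95 or 0.74. In all, 3140 genes passed (limma, BH), 1585 higher and 1555 lower, against 4937 with all corpus libraries in the fit (2225 higher, 2712 lower) and 5163 by voom (2619 higher, 2544 lower). Lower calls were also the majority with the sort-day block (1741 higher, 1818 lower), TMM scaling (1511 and 1661), no filter (1542 and 1702) and pseudocount 8 (1793 and 1871). Without Lgr5-negative library 1, 2 or 3 the count was 1620, 1372 or 1487 (63.5, 61.9 or 62.1% higher). Without EpCAM-high library 1, 2 or 3 lower calls were again the majority, with 1241, 895 or 1128 higher and 1480, 973 or 1138 lower (1868 in all without library 2). Whichever library was left out, 52 of the 73 named calls passed.

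Tuft cell genes had a median of 3.52 against Lgr5-negative cells, with 17 of 20 higher and 1 lower, also over the list alone (camera BH adjusted p = 9.38e-10, adjusted p = 0.315 with an estimated correlation). G2/M genes fell in 17 of 24 cases (22 over the list alone) and S phase genes in 19 of 26 (20 over the list alone), with Bub1b at -3.37, Ckap2l at -3.07, Cdc45 at -2.92 and Uhrf1 at -2.73 (medians -2.73 and -1.77, camera BH adjusted p = 1.18e-09 and 2.41e-09, adjusted p = 0.209 and 0.199 with an estimated correlation). Enteroendocrine genes fell in 15 of 23 cases and 1 rose (21 and 1 over the list alone), with a median of -3.66, or -3.63 at the bound, histidine decarboxylase (Hdc) at -3.72 and glucagon (Gcg) at least 698-fold lower (camera BH adjusted p = 2.19e-09, adjusted p = 0.152 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 23 cases (20 over the list alone, Myc at -2.35) and mucous neck genes in 5 of 8, also over the list alone (Muc6 at -2.68, Galnt6 at -2.74), with medians of -1.08 and -1.998 (camera BH adjusted p = 1.73e-08 and 0.000687, adjusted p = 0.107 and 0.209 with an estimated correlation). Stem and Wnt genes (median 0.53, 5 higher and 1 lower, 6 and 1 over the list alone, Ascl2 at 3.83, Slc12a2 at -1.15), intestine (2.13, 3 of 9 higher, 4 over the list alone, Vil1 at 2.13) and endothelium (1.74, 3 of 5 higher, Tek at 5.08) passed with camera BH adjusted p = 0.0311, 0.00925 and 0.0311. By camera their values were BH adjusted p = 0.413, 0.152 and 0.265 with an estimated correlation, in that order. The oxidative phosphorylation list (0.21, 0.136) passed with the block (0.0438). Epithelial genes (median 0.28, 8 higher and 4 lower) had a median of -0.03 with TMM scaling and did not pass. Immune genes had a median of -0.95 and a mean of 0.10 (Cd79b at 5.45, and Coro1a at 3.02 with limma BH adjusted p = 0.05, 0.0515 with the block) and, like the remaining lists, did not pass.

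In the EpCAM-low Lgr5-positive libraries, medians of chief, parietal and mitochondrial genes were higher than in Lgr5-negative cells, and those of endocrine, mucous neck and cycling genes lower (camera BH adjusted p from 0.186 to 0.352 with an estimated correlation). Mug1 (7.02, SE 0.48), Chia1 (5.27, SE 0.37), Igfbp2 (4.99, SE 0.95), Apoa1 (4.85, SE 0.84) and Rdh7 (4.61, SE 0.69) rose. Sst (-6.85, SE 1.40), Pappa2 (-6.61), Racgap1 (-5.94, SE 1.72), Chgb (-5.87, SE 0.71) and Lrp1 (-5.67, SE 1.67) fell. Their limma BH adjusted p ran from 0.000187 (Mug1) to 0.0293 (Lrp1). Epcam fell by 0.96 (SE 0.17, limma BH adjusted p = 0.00368) and Sox2 differed by 0.39 (0.324). On log2(CPM + 1) values Epcam was at -2.94, and Sox2 turned to -1.34. Normalized counts summed to between 9.99e+07 and 1.88e+08 per EpCAM-low library and between 3.17e+07 and 3.54e+07 per Lgr5-negative library. A rise on this scale, of a gene or a list, therefore need not be a rise in the share of reads. In all, 4590 genes passed (limma, BH), 1915 higher and 2675 lower. TMM scaling moved the median of all genes by -0.14 log2 units and gave 1514 higher and 3122 lower. Without Lgr5-negative library 1, 2 or 3 the count was 2782, 2614 or 2666. Of the named genes, 78 of the 89 calls passed whichever library was left out.

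Oxidative phosphorylation genes rose in 22 of 22 cases in EpCAM-low libraries (median 1.57, Cycs at 2.50, camera BH adjusted p = 2.49e-11, adjusted p = 0.223 with an estimated correlation). Parietal genes rose in 12 of 15 cases (median 2.99, Atp4a at 4.51, Kcnq1 at 2.91) and chief cell genes in 6 of 10 with 1 lower (2.74, Gif at 3.88, Clps at 3.21), with camera BH adjusted p = 6.94e-08 and 0.0083. For these lists, camera gave BH adjusted p = 0.223 and 0.352 with an estimated correlation, in that order. The G2/M list fell in 24 of 24 cases (median -3.51, Cenpe at -4.92) and S phase in 19 of 26 (-1.61, Uhrf1 at -3.26), with camera BH adjusted p = 1.93e-09 and 1.41e-06. In camera they had BH adjusted p = 0.186 and 0.192 with an estimated correlation, in that order. Enteroendocrine genes fell in 18 of 23 cases with 1 higher (median -4.40, or -4.23 at the bound, Chga at -5.22), and tuft cell genes in 14 of 20 (19 over the list alone, median -2.28, or -2.20 at the bound, Avil at -2.69, Gnb3 at least 3.57-fold lower), with camera BH adjusted p = 5.51e-08 and 1.18e-05. Camera gave them BH adjusted p = 0.186 and 0.348 with an estimated correlation, in that order. Mucous neck genes (5 of 8 fell, median -1.998, Muc6 at -3.54) and epithelial genes (9 of 20 fell, -0.98, or -0.94 at the bound, Krt8 at -1.54) passed with camera BH adjusted p = 0.00315 and 0.00195. By camera their values were BH adjusted p = 0.209 and 0.186 with an estimated correlation, in that order. Glia (-4.43, or -3.65 at the bound, Ncam1 at -7.71), Notch (-1.81, Jag2 at -2.75), ribosome biogenesis (-0.65, Myc at -1.64) and other stem markers (-1.18, Sox9 at -1.18, Tert at least 4.44-fold lower) passed as lower with camera BH adjusted p = 0.00211, 0.00315, 0.00315 and 0.036. For these lists, camera gave BH adjusted p = 0.186 with an estimated correlation for each. Immediate early genes (-0.86, Fos at -2.88, 0.0287, adjusted p = 0.209 with an estimated correlation) fell in 7 cases and rose in 1, Jun at 1.71. Members that fell were 5 of 8 glia, 6 of 13 Notch, 6 of 23 ribosome biogenesis and 7 of 11 other stem genes. Adjusted over the list alone, 13 parietal genes rose, and 20 enteroendocrine, 20 S phase, 11 epithelial, 7 glia, 8 Notch and 11 immediate early genes fell, with counts as over all genes for the oxidative phosphorylation, chief, G2/M, neck, ribosome and other stem lists. Stem and Wnt genes (median 0.72, 6 higher and 2 lower, Tnfrsf19 at 3.88, Wif1 at least 16.7-fold lower) and endoplasmic reticulum genes (0.39, 7 higher and 3 lower, Xbp1 at 1.44, Pdia3 at -0.94) passed with camera BH adjusted p = 0.0111 and 0.00638. In camera they had BH adjusted p = 0.285 and 0.352 with an estimated correlation, in that order. Immune genes (-2.57, or -2.21 at the bound, 0.0659) passed with the block (0.0457). Pit (-1.41, Psca at 2.42, Muc5ac at -4.03), endothelium (0.98), squamous (-1.68, Krt13 at -2.25 with limma BH adjusted p = 0.0345, 0.0524 with the block) and intestine genes (2.40, Fabp1 at 4.51, Vil1 at -2.86) did not pass.

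The corpus Sox2 sort asked which genes go with Sox2 in the corpus. Lgr5 rose from 82.46 ± 16.35 in Sox2-negative to 459.2 ± 75.52 in Sox2-positive libraries (2.47, SE 0.23, limma BH adjusted p = 0.000298), together with Nkd1 and 15 of 20 tuft cell genes. Of 23 endocrine genes 15 fell and 1 rose: Chga fell from 622330 ± 265642 to 30320 ± 6538 and Hdc, the histamine-forming enzyme of enterochromaffin-like cells, from 50942 ± 23027 to 2363 ± 935.8. Of 14034 genes, 1365 passed (limma, BH), 239 higher and 1126 lower (17.5% higher), and 1138 changed more than 2-fold. Other genes that rose included Nkd1 (2.20, SE 0.25), Fxyd6 (1.74, SE 0.22), Plekhs1 (1.69, SE 0.23), the long noncoding RNA Firre (1.69, SE 0.39), Mctp1 (1.67, SE 0.31), Flvcr2 (1.62, SE 0.24), Pcdh20 (1.57, SE 0.22), Nebl (1.55, SE 0.23) and Fcna (1.53, SE 0.23). For these genes, limma BH adjusted p ran from 0.0007 (Nkd1) to 0.0252 (Firre). Genes that fell included the neuroendocrine peptide gene Vgf (-5.30, SE 0.36), the plasma protein genes Ahsg (-5.24, SE 0.44), Vtn (-5.01, SE 0.24) and Gc (-4.94, SE 0.32), Lhfpl5 (-4.50, SE 0.32), Nov (-4.41, SE 0.40), Pappa2 (-4.41, SE 0.27), Hdc (-4.41, SE 0.41), Chga (-4.29, SE 0.30) and the lipase-related Pnliprp1 (-4.28, SE 0.24). Their limma BH adjusted p ran from 3.92e-05 (Vtn) to 0.000863 (Hdc). The block gave 2305 calls (694 higher, 1611 lower, 30.1% higher) and the fit over all corpus libraries 542 (39 higher, 503 lower, 7.20% higher). Without Sox2-negative library 2 or 3 the count was 731 or 690. Named calls that passed whichever library was left out were 35 of 50.

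Enteroendocrine genes fell in 15 of 23 cases and 1 rose (17 and 1 over the list alone), with Gcg at -3.67, Scg5 at -3.39 and Pcsk1 at -3.62 (median -2.35, camera BH adjusted p = 2.87e-14, adjusted p = 0.381 with an estimated correlation). Tuft cell genes rose in 15 of 20 cases (19 over the list alone), with the ion channel Trpm5 at 1.44 and Bmx at 1.44 (median 1.29, camera BH adjusted p = 1.24e-14, adjusted p = 0.444 with an estimated correlation). Immune genes had a median of -3.88, with 7 of 15 lower and 1 higher (11 and 2 over the list alone), Cd52 at -5.33 and Tyrobp at -5.26 (camera BH adjusted p = 2.89e-05, adjusted p = 0.444 with an estimated correlation), whereas Ptprc was at 1.19. Chief genes (1.15, 1 of 10 higher, Cym at 4.48, 2 over the list alone), stem and Wnt genes (0.27, 3 higher, 4 and 1 lower over the list alone, Tnfrsf19 at 1.41), parietal (0.22, 1 higher, Kcnq1 at 0.57) and oxidative phosphorylation genes (0.13) passed as higher with camera BH adjusted p = 0.00264, 0.0325, 0.0278 and 0.0257. Camera gave them BH adjusted p = 0.647, 0.381, 0.752 and 0.752 with an estimated correlation, in that order. Glia genes passed as lower (-1.31, 4 of 7 fell, Ncam1 at -3.75, camera BH adjusted p = 0.00774, adjusted p = 0.381 with an estimated correlation). Mucous neck (0.22, 0.0965) and pit genes (-0.47, Gkn1 at -0.62, 0.108) passed with the block (0.0281 for both). Other stem markers (0.16, mean -0.22, Runx1 at 0.52, Cckbr at -3.33), S phase (-0.00, mean 0.03, median 0.02 with TMM scaling), G2/M (0.03), ribosome (0.06), endoplasmic reticulum (-0.11), Notch (0.16), immediate early (-0.12), epithelium (0.02, mean -0.04), endothelium (-0.10, mean 0.10, Tek at 1.78, Plvap at -1.16), squamous (-0.06) and intestine genes (0.25) did not pass.

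**Figure D4:**
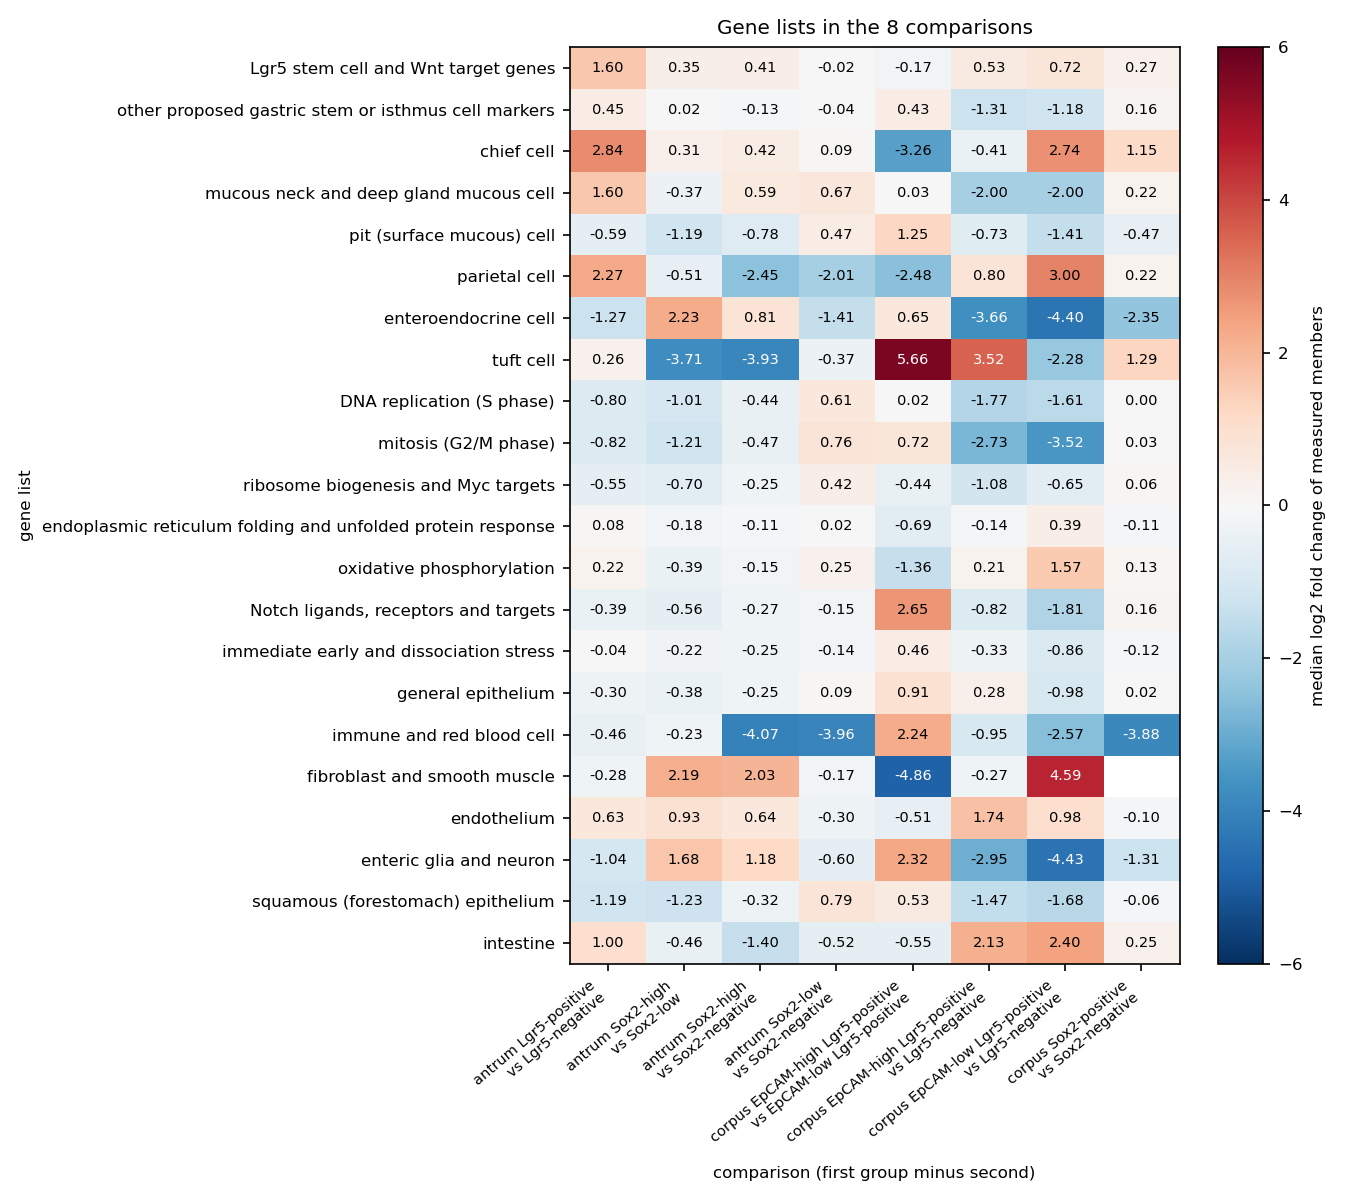
Median log2 fold change of the measured members of 22 gene lists (vertical axis) in the 8 comparisons (horizontal axis, first group minus second), with the value written in each cell and colour running from -6 to 6. Tuft cell genes run from -3.93 (antrum Sox2-high against Sox2-negative) to 5.66 (corpus EpCAM-high against EpCAM-low), and enteroendocrine genes from -4.40 to 2.23.

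Whether a sort went with different genes in the 2 tissues was tested as the antrum effect minus the corpus effect, over the 15 libraries of a line. For Lgr5 (corpus EpCAM-high against Lgr5-negative), 627 of 15539 genes passed (limma, BH), 282 with a higher and 345 with a lower antrum effect. The neck and deep gland mucin Muc6 was higher in antrum positives and lower in corpus positives (effects 4.69 and -2.66, difference 7.34, SE 0.69, limma BH adjusted p = 0.000567), as were the pepsinogen Pga5 (5.67, SE 0.69, 0.0015), the trypsin Try4 (5.51, SE 1.33, 0.0351), and Serpinf2 (5.27, SE 1.33, 0.0419), while Gif had effects of 5.89 and 0.58 (5.31, SE 0.78, 0.00377). Lrrn1 (-6.41, SE 1.25, limma BH adjusted p = 0.0138), Ap1s2 (-5.30, SE 1.02, 0.013), claudin Cldn3 (-4.88, SE 0.87, 0.00873), the transcription factor Hhex (-4.86, SE 1.18, 0.0352) and Fcna (-4.63, SE 0.80, 0.00734) had the higher effect in the corpus. Try4 belongs to a family of near-identical trypsin genes and is uncertain. Lgr5 itself differed by -1.02 (SE 0.75, limma BH adjusted p = 0.602). The block called 1456 genes (675 higher, 781 lower) and voom 1925 (939 higher, 986 lower). The majority turned by DESeq2 (745 higher, 639 lower), with all libraries in a single fit (553 and 501) and by edgeR with RLE (312 and 291) or TMM factors (308 and 297). The count was lower by over 1.5 times without antrum Lgr5-negative library 1, 2 or 3 (384, 258 or 355), corpus Lgr5-negative library 1, 2 or 3 (309, 196 or 271) or EpCAM-high library 2 or 3 (281 or 382). Higher antrum effects also became the majority without antrum Lgr5-negative library 2 or 3, antrum Lgr5-positive library 3 or EpCAM-high library 1, 2 or 3, up to 186 against 95 without EpCAM-high library 2. The calls of Try4, Serpinf2 and Hhex ended in 10, 12 and 11 of the 12 fits that each left out 1 library, with limma BH adjusted p of up to 0.0926, 0.109 and 0.103.

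For Sox2 (antrum Sox2-low and corpus Sox2-positive, each against Sox2-negative), 6 of 16564 genes passed (limma, BH), all with the higher effect in the antrum. The ghrelin acyltransferase Mboat4 had effects of 0.54 in the antrum and -3.31 in the corpus (difference 3.85, SE 0.40, limma BH adjusted p = 0.00342), and the transcription factor Nkx6-2 of 0.50 and -2.21 (2.72, SE 0.33, 0.00854). The count at an unadjusted p under 0.05 was 929, and the block called 101 (72 higher, 29 lower), DESeq2 138 (95 higher, 43 lower), voom 78 (52 higher, 26 lower) and edgeR with the block 86 (57 higher, 29 lower). It was 3 without antrum Sox2-negative library 3, antrum Sox2-low library 2 or corpus Sox2-positive library 1, and 2 without corpus Sox2-negative library 3. It was 1 without corpus Sox2-negative library 2 or Sox2-positive library 3, and in the last 2 cases the call of Nkx6-2 ended, at log2 differences of 2.51 and 2.60 (highest limma BH adjusted p = 0.053). Lgr5 differed by -2.42 (SE 0.68, limma BH adjusted p = 0.341, 0.0262 with the block).

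**Figure D5:**
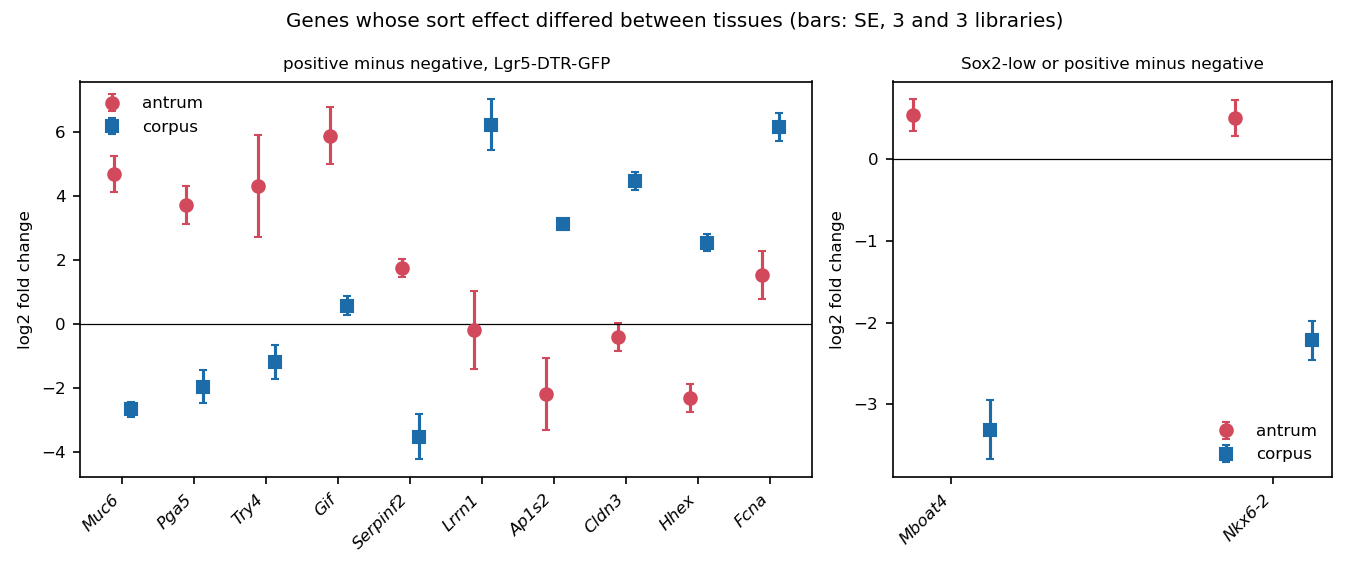
Log2 fold changes of positive (or Sox2-low) against negative libraries in the antrum (circles) and corpus (squares) for the genes named by the tissue tests, with bars at 1 SE from 3 and 3 libraries. Muc6 lies at 4.69 and -2.66, Fcna at 1.52 and 6.15, and Mboat4 at 0.54 and -3.31.

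The authors' deposited tables were compared with these fits across genes, which are not independent replicates. The authors' deposited table for Sox2-high against Sox2-low lists 831 genes with an adjusted p under 0.05 of 17515 with a value (622 positive, 209 negative), of which 648 were also called here. Log2 fold changes of the authors' deposited table correlated with those of limma at Pearson r = 0.953 and Spearman rho = 0.967 over 15064 genes. In the same authors' deposited table, the fold change column equals the square of the log2 fold change in 86.4% of 24942 values and 2 to its power in 0.0882% (relative tolerance 0.001), so it was not used as a fold change. The authors' deposited table for antrum Lgr5 lists 152 genes of 16554 (17 positive, 135 negative), with r = -0.957 and rho = -0.967, so its positive values stand for genes higher in Lgr5-negative cells. In the authors' deposited table for the corpus EpCAM comparison, 2929 of 16355 genes have an adjusted p under 0.05 (1100 positive, 1829 negative). For the authors' deposited table of this pair r was -0.564 and rho -0.632 over 14847 genes.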

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

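The count of regroupings that exchanged tissues unequally and the splits that kept sort-day pairs together were chosen only after the regrouping counts were seen. The 2 tests of a tissue difference picked out the following genes, because the antrum effect of a sort differed from its corpus effect in a test of that difference (limma with Benjamini-Hochberg adjustment, 12 libraries behind each difference).

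For Lgr5-positive against Lgr5-negative cells, 627 genes differed. The effect was higher in the antrum for Muc6 (log2 difference 7.34), Pga5 (5.67), Try4 (5.51), Gif (5.31) and Serpinf2 (5.27). It was higher in the corpus for Lrrn1 (-6.41), Ap1s2 (-5.30), Cldn3 (-4.88), Hhex (-4.86) and Fcna (-4.63). For Sox2, 6 genes differed, among them Mboat4 (3.85) and Nkx6-2 (2.72).

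The corpus Lgr5-positive cells in this test were gated on high EpCAM and the antral ones were not, so tissue and gate cannot be separated. The corpus Sox2-positive gate was set beside the antral Sox2-low gate. Description labels call both gates low but do not say whether they were set alike, so tissue and gate cannot be separated there either. When the tissue labels were regrouped at random, 7 of 100 regroupings, the real one included, gave as many genes as the Lgr5 test, with 1233 the highest other count. For Sox2, 9 of 100 gave as many as the real 6, with 3031 the highest other count. The 6 and 8 other regroupings with as many genes all exchanged tissues unequally between positive and negative cells, as 59 and 60 of the 99 others did, and regroupings that exchanged them equally called 0 genes at most. Counts of 1233 and 3031 point to a structure of the libraries: those draws put 2 and 3 corpus libraries among the antrum negatives and 0 among the positives. Differences between the tissues themselves are a candidate explanation of such draws, so the 7 and 9 of 100 do not measure chance alone. With the positive and negative library of a sort day kept together, 1 of 10 splits, the real one, gave as many genes in each test (627 and 6, highest other 0 in both). For a share under 0.05, 10 splits are too few. All other splits of these pairs, and the equal exchanges, mixed antrum and corpus libraries within a group. Tissue differences then add to the spread within groups, so their counts of 0 do not measure chance either. With the sort-day block the real counts were 1456 and 101.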

How the results depend on the processing

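Chosen only after the data were seen were edgeR with TMM factors and block, TMM scaling, the pseudocounts of 8 and 0.5, the fit without antrum sort day 1 and leaving libraries out of the list counts. The edgeR fit with TMM factors and no block was the test of the initial design, run later on recovered reads. In the antrum it called 0 genes for Lgr5, 974 for Sox2-high against Sox2-low, 200 for Sox2-high and 0 for Sox2-low against Sox2-negative. In the corpus it called 4239 for EpCAM-high against EpCAM-low, 2984 for EpCAM-high and 4048 for EpCAM-low against Lgr5-negative, and 1359 for Sox2. The Lgr5 and Sox2 tissue differences gave 605 and 4. Over the 10 gene counts, pseudocount 0.5 kept all within 1.5 times, as TMM scaling did in the 8 where it was run. No named gene changed direction where the main fit or the other setting called it. Sox2 reversed on the log2(CPM + 1) scale in 2 comparisons. With 1 library left out, 2835 values of named genes kept their side of the threshold and direction, 464 were no longer past it and 5 came past it. Another 93, without a call in either fit, changed direction. Such changes without a call also came in 7 values by DESeq2, 9 by voom and 9 by edgeR with RLE factors. The cause was not tested for any change given here.

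For antrum Lgr5 the 0 calls became 446 with the sort-day block, 400 by edgeR with block, 373 by DESeq2, 169 by voom, 77 with all libraries and 12 without a filter. In its simulation, 33.6% of DESeq2 and 10% of limma calls were false, and limma found 0% of 2-fold changes. This need not hold for paired sort days. Sox2-high against Sox2-low went from 1190 to 4581 with the block, 4196 by edgeR with block, 2457 by DESeq2, 6255 by voom and 4440 without sort day 1. Sox2-high against Sox2-negative went from 324 to 1463 with the block, 1095 by edgeR with block, 1050 by DESeq2, 1493 by voom and 1482 without sort day 1. It was 200 by edgeR with TMM and 204 with RLE factors. Sox2-low against Sox2-negative went from 0 to 241 by DESeq2 and 321 by voom. EpCAM-high against Lgr5-negative went from 3140 to 4937 with all libraries and 5163 by voom. Corpus Sox2 went from 1365 to 2305 with the block, 2388 by edgeR with block and 542 with all libraries. The Lgr5 tissue difference went from 627 to 1456 with the block, 1288 by edgeR with block, 1384 by DESeq2, 1925 by voom, 1054 with all libraries and 997 with pseudocount 8. The Sox2 tissue difference went from 6 to 101 with the block, 86 by edgeR with block, 138 by DESeq2, 78 by voom, 13 with all libraries, 14 without a filter and 14 with pseudocount 8. Beyond the values given beside the results, the block changed no call of a list or of a gene whose value is given.

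With an estimated correlation 0 lists passed in each of the 8 comparisons, against 14, 9, 13, 8, 7, 9, 16 and 8 at the preset value (antrum Lgr5, Sox2-high against Sox2-low, Sox2-high and Sox2-low against Sox2-negative, EpCAM-high against EpCAM-low, EpCAM-high and EpCAM-low against Lgr5-negative, corpus Sox2). With 1 library left out these list counts ran, in that order, from 10 to 14, 7 to 10, 9 to 14, 6 to 9, 7 to 10, 8 to 11, 15 to 17 and 6 to 10. The gene counts ran from 0 to 4, 239 to 1409, 87 to 225, 0 to 0, 2985 to 4735, 1372 to 2721, 2614 to 4902 and 690 to 1238, and for the Lgr5 and Sox2 tissue differences from 196 to 715 and 1 to 8.

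On log2(CPM + 1) values with unadjusted library sizes, Sox2 reversed from 0.29 to -0.14 in antrum Lgr5 and from 0.39 to -1.34 in EpCAM-low against Lgr5-negative. Epcam went from 0.53 to 0.095 in antrum Lgr5. In EpCAM-high against EpCAM-low, Lgr5 went from 1.04 to 2.98, Sox2 from 0.64 to 2.33 and Epcam from 2.06 to 4.06. In EpCAM-low against Lgr5-negative, Lgr5 went from 4.53 to 2.15 and Epcam from -0.96 to -2.94, and Lgr5 in corpus Sox2 from 2.47 to 2.13. The other 15 sort marker values moved by less than the spread between libraries. The EpCAM-low libraries had 31985198 to 62344916 reads, but Pgc alone took 43.1% of them, which limits the depth left for other genes there.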

Other observations

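Chosen only after the result was seen were both tests of the authors' deposited EpCAM table and, as values of Chga, Tph1 and Dclk1 were already known, the tests of few cells, of chief cell transcripts and of fewer detected genes. The test of non-epithelial cells and the splits of libraries were written down ahead of the values they measured, but after the gene counts of the comparisons were known.

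Endocrine transcripts were unevenly spread over the sorts. Chga and Chgb took 2.67 ± 0.651% and 6.78 ± 1.29% of the reads (SD, n = 3) in antrum Sox2-high libraries. In corpus Sox2-negative libraries Chga took 2.78 ± 1.17% and Chgb 0.140 ± 0.0682%. Gastrin took 9.68 ± 8.86% in antrum Sox2-negative libraries, with 19.5% in library 1.

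The endocrine rise in Sox2-high over Sox2-low libraries was weighed against 2 technical explanations. If few sorted cells per library raised these genes in either tissue, they would be higher in the corpus EpCAM-high libraries, which also came from few cells. Of the 925 genes higher in Sox2-high, 750 were tested there. Their median log2 fold change against Lgr5-negative cells was -0.70, against 2.42 in the antrum, with 85 called higher and 187 lower. This cannot decide, because the 2 corpus groups also differ in their endocrine content. Chga took 0.529% of the reads in Lgr5-negative and 0.0383% in EpCAM-high libraries (means). Few cells therefore stay open as an explanation. Non-epithelial cells in the gate also remain open: the immune list had a median of -0.23, but fibroblast genes (2.19, on 3 genes) lay higher, as did endothelial genes (0.93), whose members went both ways. The Sox2 gate itself stays open as a biological explanation and was not tested.

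The tuft cell rise in EpCAM-high over EpCAM-low Lgr5-positive libraries was also weighed against 2 technical explanations. Chief cell transcripts filling the EpCAM-low libraries might lower other epithelial genes alike. The tuft median exceeded that of general epithelium by 4.87 log2 units with TMM scaling and by 4.76 with deposited scaling. This cannot decide: chief cells may share epithelial genes. This cause stays open. Fewer detected genes in the EpCAM-low libraries could not raise tuft genes in EpCAM-high over Lgr5-negative libraries, where the tuft median was 3.52. That value does not involve the EpCAM-low libraries. It cannot tell how much of their difference from EpCAM-high came from fewer detected genes, so this explanation stays open. The EpCAM gate itself stays open as a biological explanation and was not tested.

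In the authors' deposited table for the corpus EpCAM pair, the log2 fold changes correlated with those of EpCAM-high against EpCAM-low at a size of only 0.564 across genes. The highest correlation of the authors' deposited table with another pair of groups was 0.908, for EpCAM-low minus corpus Lgr5-negative libraries. Of 54 exchanges of 1 library tried, 14 raised the correlation with the authors' deposited table, each with an antrum library in place of a corpus Lgr5-negative one. The highest was 0.931, with antrum Lgr5-positive library 3 in place of corpus Lgr5-negative library 1, and the next 0.925, so no single exchange stands out. The table may hold another comparison than its name says, and an exchanged library stays open. No biological explanation was tested, and the libraries used here keep their labels.

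The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes as in the real split were called in 10 of 10 splits for antrum Lgr5 (0 genes, highest other 0) and for Sox2-low against Sox2-negative (0, highest other 0). For the 6 remaining comparisons it was 1 of 10, the real split itself: Sox2-high against Sox2-low (1190, highest other 0), Sox2-high against Sox2-negative (324, highest other 1), EpCAM-high against EpCAM-low (4714, highest other 0), EpCAM-high against Lgr5-negative (3140, highest other 0), EpCAM-low against Lgr5-negative (4590, highest other 0) and corpus Sox2 (1365, highest other 8). The real split and 3 others part every sort day, and with the sort-day block the highest of these 3 was 1 gene (corpus Sox2, real 2305) and 0 in the other comparisons (real 446 for antrum Lgr5).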
